A study of Mus musculus with 36 samples.

How the data were processed

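Each library is the ligated left carotid artery of 1 mouse, collected 14 days after ligation, as 2 strains by 2 regimens by 3 treatments with 3 mice per group. Doses per the labels were vehicle at 2 mL/kg/day, valsartan at 27 mg/kg/day and sacubitril/valsartan at 60 mg/kg/day. RNA was extracted with Trizol and RNeasy Micro columns and sequenced from stranded mRNA libraries on an Illumina HiSeq instrument, per the labels. The authors trimmed reads with Trimmomatic 0.36 and aligned them to GRCm38 with STAR 2.5.2b, per the submitters' processing notes. Counts per gene symbol were made by the authors with featureCounts of Subread 1.5.0p3, per the same notes, and the annotation release and strand setting are not given. Starting point here was the deposited table of counts, 49568 symbols by 36 libraries, of which 47313 symbols are in GENCODE M21. No entry of the table lacked a gene name, and all 36 columns matched a library. No reads were aligned here, so library layout, mapping rate and duplication were not examined.

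Total counts ran from 18.96 M to 28.97 M (median 22.78 M), detected genes per library from 21810 to 24470 (median 22870), and the 10 highest genes held 5.32 to 18.8 percent of counts (median 11.9). Mitochondrially encoded genes held 2.31 to 12.1 percent. All 36 libraries were kept. Genes were filtered with filterByExpr of edgeR over the 12 groups, which left 18628, and TMM factors ran from 0.82 to 1.13. All comparisons came from 1 edgeR quasi-likelihood fit of 12 group means with 24 residual degrees of freedom (R 4.3.3, edgeR 4.0.16, prior not robust). The biological coefficient of variation was 0.463 and the prior degrees of freedom 2.36. A gene passed at a Benjamini-Hochberg adjusted p below 0.05, adjusted within each comparison. The standard error given with a log2 difference is derived from the quasi-likelihood F and the intervals are 95%.

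The 21 comparisons were strain under vehicle (129X1 minus B6, mean over regimens), regimen under vehicle (therapeutic minus prophylactic, mean over strains), Sac/val minus vehicle, Val minus vehicle and Sac/val minus Val as means over 4 strata and within each stratum, and the interactions of both drug differences with strain and with regimen. The 32 gene lists were written from general knowledge of cell types and pathways. They were tested with camera of limma 3.58.1 on log2 CPM, the counts scaled to the same library total (prior count 2), with the preset correlation of 0.01, with an estimated correlation and with fry, each adjusted over the 32 lists. Where a count is said to be adjusted over the list alone, edgeR p values were adjusted over the members of that list only. Medians and means of a list are over its tested members, and not every list member was tested: 13 of 16 renin-angiotensin genes and 15 of 17 natriuretic peptide genes were.

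Genes are named by rule: Mme, Agtr1a and Npr3 in every comparison, with Nnt for strain. Added to them were the 8 largest differences per direction at or above 5 CPM with library sets that do not overlap and up to 4 passing members per list with the smallest p. Where no gene passed, the 3 smallest p values at or above 5 CPM were named. A few genes that this rule selects are not reported. Where every library on 1 side had 3 counts or fewer, the ratio of summed counts is given with an interval that covers counting error only. Coordinates of the named genes follow GRCm38 and are 1-based.

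The alternatives fixed at the start were DESeq2 size factors in edgeR, the DESeq2 1.42.0 Wald test, no filter, only the libraries compared, 3 list scores as covariates (skeletal muscle, adipocyte, Schwann cell), the animal number as covariate, and leaving out each library in turn. For lists they were the estimated correlation, fry, a prior count of 0.5 and the 3 scores. Chosen after seeing the data were 6 list scores as covariates (T and NK cell, B and plasma cell, skeletal muscle, thyroid, adipocyte, sympathetic neuron and glomus cell), limma voom with sample quality weights with and without those 6 scores, the 6 scores moved at random between libraries, a robust prior, a fit without the 16 libraries at or above 10 CPM of Rag1, and the strain contrast in the drug-treated libraries. The strain contrast within each regimen of the vehicle libraries was also chosen after seeing the data. Label splits, up to 100 per comparison and 10 within a stratum, moved whole libraries between the groups compared.

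The main test was tried on simulated counts of 18628 genes with 50 genes changed at each of log2 sizes 0.5, 1, 2 and 3. In the strain layout it called 2, 38, 68 and 82 percent of them, in the mean over 4 strata 22, 70, 92 and 92 percent, and within a stratum 2, 28, 62 and 86 percent. Of 18408 unchanged genes it called 7, 7 and 3, and DESeq2 called 39, 30 and 18. Genes were simulated independently of each other, without the differences in tissue content between the real libraries. These figures therefore do not cover calls that arise when many genes move together. Sex was not tested as a factor, and measures of the vessel wall or of blood pressure were not analysed here.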

Results

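The ligated left carotid artery of mice of 2 inbred strains, C57BL/6J (B6) and 129X1/SvJ (129X1), was profiled by RNA sequencing 14 days after ligation, an operation that stops flow and drives wall remodelling. Mice were given vehicle, the angiotensin receptor blocker valsartan (Val) or sacubitril/valsartan (Sac/val), which also inhibits the peptidase neprilysin, encoded by Mme. Dosing was prophylactic (16 days, starting 2 days ahead of ligation) or therapeutic (7 days, starting on day 7). The 12 groups held 3 libraries each, 36 in all, and each combination of strain and regimen is called a stratum below. Total counts per library ran from 18.96 M to 28.97 M (median 22.78 M), and 18628 of 49568 gene symbols were tested. The Y-linked gene Ddx3y was at or above 46.0 CPM and Xist, the transcript of the silenced X chromosome, at or below 0.245 CPM in every library, the pattern of male mice. The median half-width of the 95% interval of a log2 difference was 0.54 in the strain comparison, 0.38 in the means over 4 strata and 0.76 within a stratum.

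Transcripts of tissues that lie beside the carotid varied widely between libraries of the same group. Rag1, which recombines antigen receptor genes in developing lymphocytes, was at or above 10 CPM in 16 of 36 libraries and reached 1738 CPM in a B6 Val prophylactic library. Those libraries were 12 of 18 from 129X1 and 4 of 18 from B6 (Fisher's exact test p = 0.0176, adjusted p = 0.0528). By treatment they were 6 of 12 vehicle, 6 of 12 Val and 4 of 12 Sac/val (exact p = 0.762), and the exact p for regimen was 0.315. Thyroglobulin (Tg) ran from 0.141 to 42480 CPM, skeletal muscle actin (Acta1) from 2.22 to 9450 CPM and the brown fat uncoupling protein Ucp1 from 76.2 to 3213 CPM. The smooth muscle myosin Myh11 ran from 37.1 to 655 CPM. The first principal component, with 31.7% of the variance, was led by the thymus genes Prss16, H2-T3 and Rag1.

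**Figure D1:**
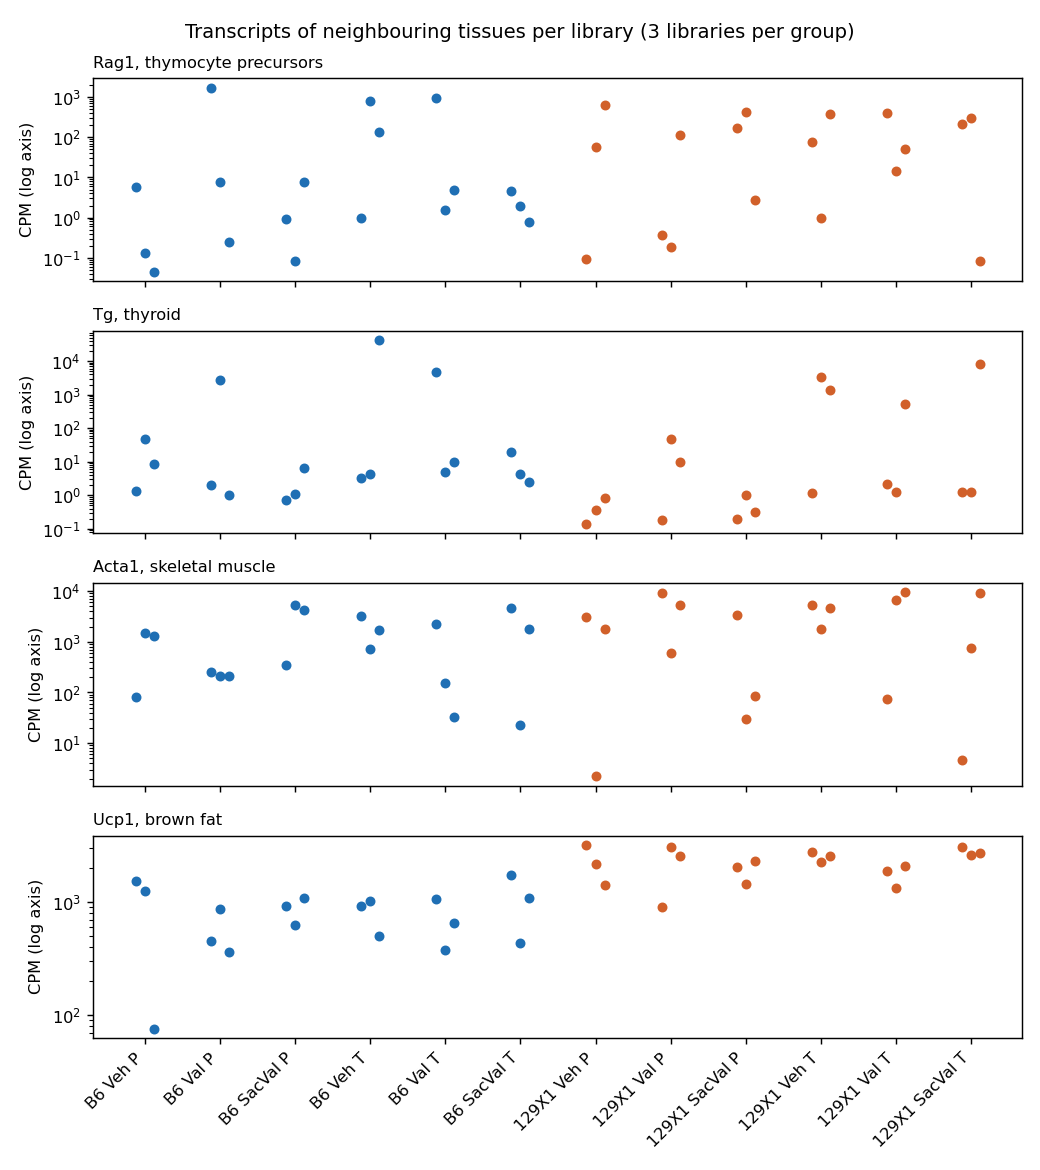
CPM (log axis) of Rag1, Tg, Acta1 and Ucp1 in each of the 36 libraries, arranged in the 12 groups, 1 point per library. Points of the same group lie far apart: Tg spans 0.141 to 42480 CPM and Rag1 reaches 1738 CPM.

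The strain comparison asks which genes differ between 129X1 and B6 ligated carotids under vehicle (6 libraries per strain, both regimens pooled with equal weight). Lox, Fcgr1, Ccl7 and Bst2 were among the genes lower in 129X1. Lox, which crosslinks collagen and elastin, was at 75.8 ± 21.7 CPM (mean ± SD) in 129X1 and 381 ± 208 CPM in B6 (log2 difference -2.33, SE 0.45, adjusted p = 0.000798). The high-affinity Fc receptor of macrophages, Fcgr1, differed by -2.54 (SE 0.44, adjusted p = 0.00023). The monocyte attractant Ccl7 differed by -2.85 (SE 0.65, adjusted p = 0.00396) and the interferon-induced tetherin Bst2 by -1.32 (SE 0.24, adjusted p = 0.000451). Higher in 129X1 were the metalloproteinase inhibitor Timp4 (1.64, SE 0.32, adjusted p = 0.000974), the brown fat elongase Elovl3 (2.25, SE 0.53, adjusted p = 0.00542) and the complex I subunit Ndufs1 (0.96, SE 0.27, adjusted p = 0.0191). By edgeR 2522 of 18628 genes passed, 1308 higher and 1214 lower in 129X1, and 5358 had an unadjusted p under 0.05. DESeq2 called 3331, against 1093 with 3 list scores as covariates, 715 without the libraries at or above 10 CPM of Rag1 and 1438 without B6 vehicle prophylactic replicate 3. In 1278 of the 2522 genes the library values of the strains did not overlap. Chance separates 0.216 percent of unselected genes so, which is no expectation for genes already called.

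Mme, the sacubitril target, was higher in 129X1, at 110 ± 29.1 CPM against 48.0 ± 19.6 CPM in B6 (log2 difference 1.19, SE 0.31, adjusted p = 0.0116, n = 6 per strain). Its call was lost with the skeletal muscle, adipocyte and Schwann cell scores as covariates (0.40, adjusted p = 0.263). Nnt, the mitochondrial transhydrogenase gene that lacks several exons in C57BL/6J, was at 32.7 ± 7.85 CPM in 129X1 and 21.3 ± 3.83 CPM in B6 (0.61, SE 0.19, adjusted p = 0.0325), a call lost in 6 of 12 fits that each left out 1 library (adjusted p up to 0.107). The angiotensin receptor Agtr1a (0.61, SE 0.25, adjusted p = 0.106) and the natriuretic peptide clearance receptor Npr3 (0.57, SE 0.32, adjusted p = 0.231; -0.21 with those 3 scores) did not pass.

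**Figure D2:**
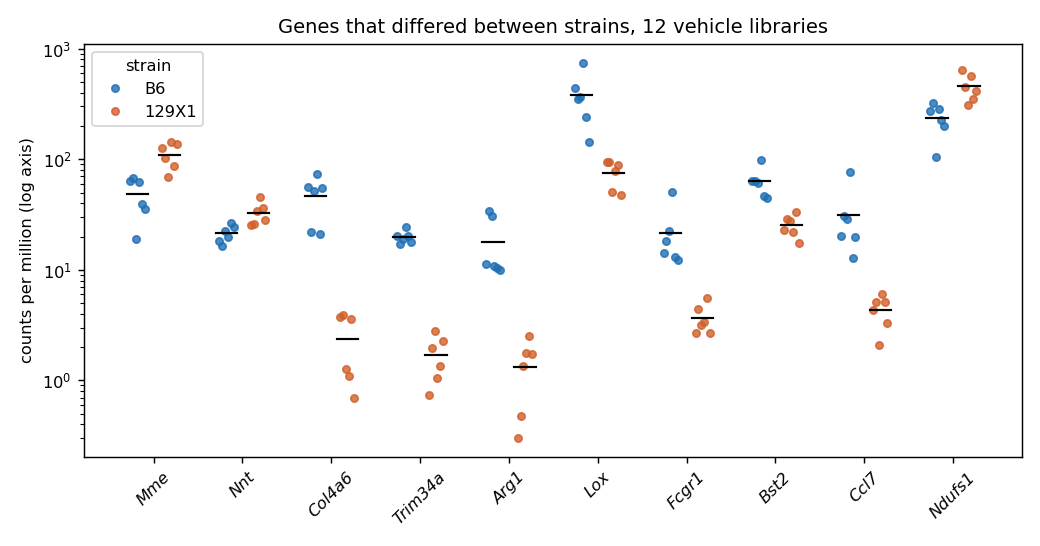
CPM (log axis) of 10 genes in the vehicle libraries of B6 and 129X1, 6 points per strain, with bars at the group means. Lox lies at a mean of 381 CPM in B6 and 75.8 CPM in 129X1, and Mme at 48.0 and 110 CPM.

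The largest differences per direction included members of gene families and genes with near-identical copies. Near silent in B6 were BC018473 (10.90, SE 1.00, 7270 against 3 counts, ratio 2420, 95% counting interval 827 to 11700), Eno1b (10.60, SE 0.44, 14187 against 9 counts, ratio 1570, interval 828 to 3440) and Rps3a3 (8.76, SE 0.33, adjusted p = 4.6e-17). BC018473 is annotated as antisense and the strand setting of the counting is not known, Eno1b and Rps3a3 are copies of Eno1 and Rps3a1, and all 3 are uncertain. Also higher were the interferon-inducible Ifi202b (8.74, SE 1.24) and Gbp2b (7.63, SE 0.49), the antiprotease Serpina1b (7.63, SE 0.48), the regulator of GTP cyclohydrolase Gchfr (6.98, SE 0.41) and BC002163 (5.76, SE 0.28), a processed copy of the complex I gene Ndufs5. Ndufs5 itself was lower (-4.18, SE 0.30), but summed with its copy the pair was higher in 129X1 (0.86, SE 0.26), so both values are uncertain. Near silent in 129X1 was the antiviral family member Trim12a (-11.24, SE 0.60, 1 against 3646 counts, ratio 3660, interval 656 to 144000). Its relatives Trim30d (-5.83, SE 0.46) and Trim34a (-3.53, SE 0.35) and the growth regulator Slfn8 (-4.53, SE 0.44) were lower as well. Reads of the Trim, Slfn, Gbp, Ifi202 and Serpina1 families can be shared between members, so these values are uncertain. Among single genes, the basement membrane collagen Col4a6 was at 2.38 ± 1.499 CPM in 129X1 and 46.5 ± 20.9 CPM in B6 (-4.34, SE 0.47, adjusted p = 1.42e-07). The cartilage collagen Col2a1 (-4.28, SE 0.81, adjusted p = 0.000579) and the arginase of alternatively activated macrophages Arg1 (-3.79, SE 0.81, adjusted p = 0.00223) were also lower.

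Matrix lists and the modulated smooth muscle list were lower in 129X1 by camera with the preset correlation, and with an estimated correlation 0 of the 32 lists passed (smallest adjusted p = 0.609). With the skeletal muscle, adipocyte and Schwann cell scores as covariates the fibrillar matrix (adjusted p = 0.0176), modulated smooth muscle (0.0198) and TGF-beta lists (0.0179) still passed, and those of matrix proteases (0.262), chondrocytes (0.279) and adventitial fibroblasts (0.416) did not. Of the genes named here Lox, Thbs1, Col8a1, Timp4, Comp and Col2a1 kept their calls with those scores and the others lost them. Fry passed modulated smooth muscle (0.0191), TGF-beta (0.0266) and chondrocyte genes (0.023) but not fibrillar matrix (0.0576). The fibrillar matrix list had a median log2 difference of -1.11 over 26 genes (camera adjusted p = 3.43e-06, adjusted p = 0.609 with an estimated correlation), with 6 genes passing over all genes and 17 adjusted over the list alone, all lower. Its leading genes were Lox, the lysyl oxidase Loxl3 (-1.47), the elastin-binding Emilin1 (-1.38) and elastin itself (Eln, -2.84, SE 0.82, adjusted p = 0.022). The modulated smooth muscle list, genes raised when contractile cells turn to repair, had a median of -1.04 (adjusted p = 9.27e-05, and 0.609 with an estimated correlation; 6 of 14 lower, 8 adjusted over the list alone), led by Thbs1 (-2.07, SE 0.39, adjusted p = 0.000594), Col8a1 (-2.17) and Tnfrsf11b (-2.14). TGF-beta genes had a median of -0.77 (adjusted p = 0.000242, and 0.609 with an estimated correlation; 5 of 17 lower, 8 adjusted over the list alone), among them Ctgf (-1.88), Cyr61 (-1.74) and Ltbp2 (-1.10). Matrix proteases and inhibitors had a median of -0.86 (adjusted p = 0.000242, and 0.609 with an estimated correlation), with 6 of 26 lower, Mmp13 (-3.79), Mmp8 (-2.28) and Timp1 (-2.04) among them, and Timp4 higher, against 12 lower and 1 higher adjusted over the list alone. Chondrocyte genes had a median of -1.03 (adjusted p = 0.0178, and 0.609 with an estimated correlation; 3 of 12 lower, 6 adjusted over the list alone), with Comp (-2.71) and Acan (-1.90) beside Col2a1. Adventitial fibroblast genes had a median of -0.69 (adjusted p = 0.0432, and 0.75 with an estimated correlation), with Fbln1 (-1.36) the 1 gene of 15 that passed. On leaving out 1 library the adventitial list lost its camera call in 6 of 12 fits (adjusted p up to 0.23). The chondrocyte list lost it in 2 (up to 0.054). The contractile smooth muscle list did not pass (median -0.13, adjusted p = 0.478). Within each regimen (3 libraries per strain), camera passed matrix proteases (adjusted p = 5.53e-06), chondrocytes (0.0101) and adventitial fibroblasts (0.0144) under prophylactic vehicle. Under therapeutic vehicle these did not pass (0.151, 0.124 and 0.357). The fibrillar matrix, modulated smooth muscle and TGF-beta lists passed in both. With an estimated correlation the smallest adjusted p of any list was 0.583. Without B6 vehicle therapeutic replicate 1 the calls of Loxl3, Emilin1, Eln, Tnfrsf11b, Ctgf, Cyr61, Ltbp2, Timp1 and Fbln1 were lost, and without 129X1 vehicle therapeutic replicate 3 those of Eln, Tnfrsf11b, Ltbp2, Mmp8, Timp1, Acan and Fbln1. Over the fits that left out 1 library, Tnfrsf11b was as small as -1.13 (adjusted p up to 0.167) and Eln as small as -2.09 (adjusted p up to 0.0888).

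Inflammatory lists were also lower in 129X1 by the same camera test, and none of them passed with an estimated correlation (0.609 for each). With the 3 scores as covariates the lists of interferon response (adjusted p = 2.38e-08), cytokines (0.00778) and immediate early genes (0.0198) still passed, and those of macrophages (0.188) and neutrophils (0.204) did not. Ptgs2, Aif1, Ms4a7, C1qa, Fosb, Zfp36, S100a8, S100a9, Retnlg and Mpo lost their calls with those scores, and the other genes named here kept them. Cytokine and adhesion genes had a median of -1.69 over 22 genes (adjusted p = 3.58e-06, and 0.609 with an estimated correlation), with 10 lower over all genes and 18 adjusted over the list alone. They included Ccl7, the prostaglandin synthase Ptgs2 (-2.36), Cxcl10 (-2.10) and the leukocyte adhesion molecule Vcam1 (-1.11). Interferon response genes had a median of -1.32 (adjusted p = 5.64e-06, and 0.609 with an estimated correlation), with 12 of 19 lower, Oasl2 (-1.55) and Oas1a (-1.66) among them, and Xaf1 higher (1.04, adjusted p = 0.00166), against 16 lower and 1 higher adjusted over the list alone. Macrophage genes had a median of -0.88 (adjusted p = 0.000242, and 0.609 with an estimated correlation; 7 of 18 lower, 9 adjusted over the list alone), led by Fcgr1, Aif1 (-1.39), Ms4a7 (-1.62) and the complement gene C1qa (-1.28). Immediate early genes, switched on within minutes of stimulation, had a median of -0.81 (adjusted p = 0.000242, and 0.609 with an estimated correlation; 6 of 14 lower, 8 adjusted over the list alone), led by Nr4a1 (-1.97, adjusted p = 6.74e-05), Egr1 (-1.29), Fosb (-1.999) and Zfp36 (-0.81). Neutrophil genes had a median of -1.49 (adjusted p = 0.0164, and 0.609 with an estimated correlation), with S100a8 (-3.63), S100a9 (-3.72) and Retnlg (-2.87) lower and Mpo (2.75) higher, against 6 lower and 1 higher of 13 adjusted over the list alone. Within each regimen, camera passed neutrophil genes under prophylactic vehicle (median -2.41, adjusted p = 0.000379) but not therapeutic (-0.67, adjusted p = 0.739). Macrophage genes also passed under prophylactic vehicle alone (adjusted p = 9.54e-06 against 0.0875). The cytokine, interferon and immediate early lists passed in both regimens. Whether these differences depend on regimen was not tested. On leaving out 1 library, Cxcl10 was as small as -1.36 and Egr1 as small as -0.825, with calls kept. Fosb was as small as -0.999 (adjusted p up to 0.181; the call was lost without B6 vehicle prophylactic replicate 2, B6 vehicle therapeutic replicate 1 or 129X1 vehicle therapeutic replicate 3) and Mpo reached an adjusted p of 0.115.

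**Figure D3:**
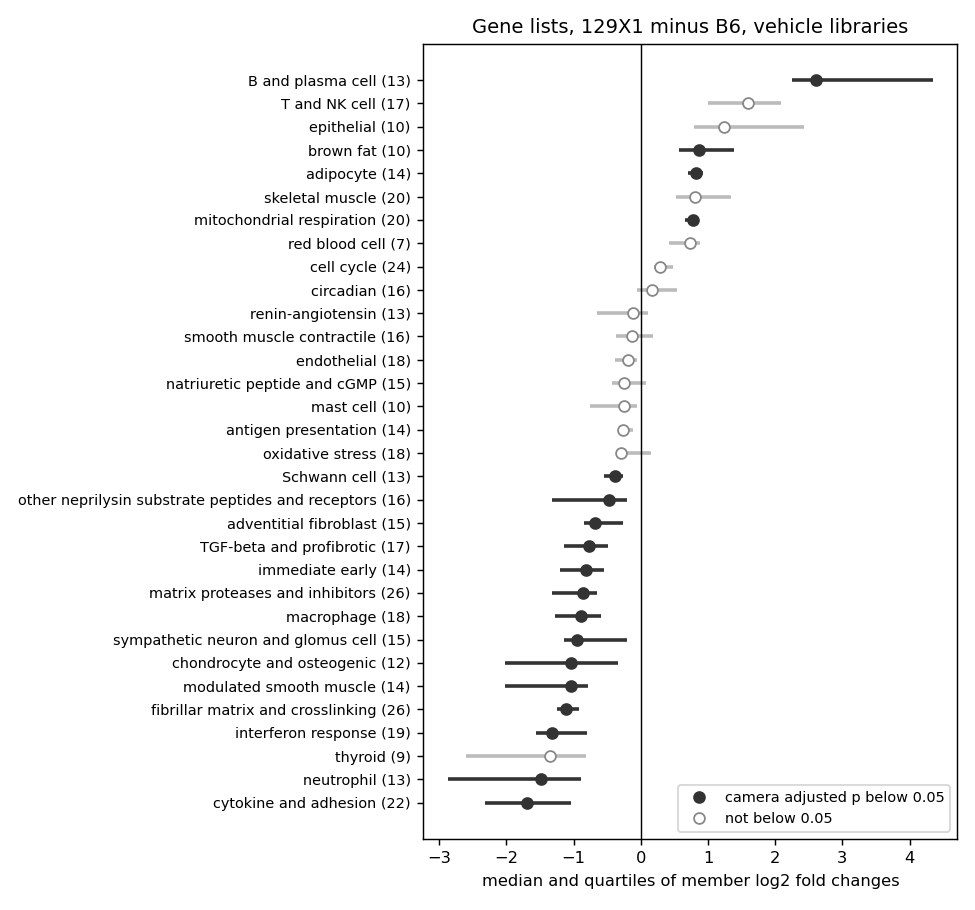
Median log2 difference (129X1 minus B6, vehicle, 6 libraries per strain) of each of 32 gene lists, with bars from the lower to the upper quartile of the genes; filled points had a camera adjusted p below 0.05. Cytokine and adhesion genes (-1.69) and fibrillar matrix genes (-1.11) lie left of 0 and mitochondrial respiration (0.78) and adipocyte genes (0.83) to the right.

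Lists of fat and of respiration were higher in 129X1 by camera with the preset correlation and did not pass with an estimated one. Mitochondrial respiration genes had a median of 0.78 (adjusted p = 7.59e-07, and 0.609 with an estimated correlation; 6 of 20 higher, 18 adjusted over the list alone), with Ndufv1 (0.88), Atp5a1 (0.78) and Uqcrc2 (0.88) beside Ndufs1. Adipocyte genes had a median of 0.83 (adjusted p = 0.000711, and 0.609 with an estimated correlation), with 6 of 14 higher, the lipid synthesis gene Acaca (1.38), the lipases Lpl (0.83) and Lipe (0.92) among them, and the hormone gene Retn lower (-1.19), against 11 higher and 1 lower adjusted over the list alone. Brown fat genes had a median of 0.86 (adjusted p = 0.0013, and 0.609 with an estimated correlation; 3 of 10 higher, 3 adjusted over the list alone): Ucp1, at 2526 ± 897 against 884 ± 536 CPM (1.52, adjusted p = 0.035), Elovl3 and Otop1 (1.49). With the muscle, adipocyte and Schwann cell scores as covariates the mitochondrial median was 0.09 (adjusted p = 0.34), and the brown fat list (0.629) did not pass. Without the libraries at or above 10 CPM of Rag1 the adipocyte and brown fat lists did not pass camera, at medians of 0.76 and 0.78. The mitochondrial list still passed there, at a median of 0.79. B and plasma cell genes had a median of 2.61 (adjusted p = 0.0413, and 0.75 with an estimated correlation; 7 of 13 higher, 11 adjusted over the list alone), among them Cr2 (5.39), Ms4a1 (4.61) and Cd79a (4.12), whose 129X1 means rest on a pair of libraries, vehicle prophylactic replicate 2 and vehicle therapeutic replicate 2. The B and plasma cell list lost its camera call in 5 of 12 fits that each left out 1 library (adjusted p up to 0.459). On leaving out 1 library Cr2 was as small as 2.67, Ms4a1 as small as 1.88 and Cd79a as small as 1.36 (adjusted p up to 0.386), and the calls of Ndufs1, Ndufv1, Atp5a1, Uqcrc2, Lpl, Lipe and Ucp1 were each lost in at least 3 of 12 such fits (adjusted p up to 0.154).

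Sympathetic neuron and glomus cell genes (median -0.96, adjusted p = 0.0268, and 0.75 with an estimated correlation) and Schwann cell genes (-0.38, adjusted p = 0.0493, and 0.75 with an estimated correlation) held 0 passing genes. In 12 camera fits that each left out 1 library, the sympathetic list was lost in 3 (adjusted p up to 0.187). The Schwann cell list was lost in 6 (up to 0.243). With the muscle, adipocyte and Schwann cell scores as covariates the sympathetic median was 1.07 (camera adjusted p = 0.927). The sympathetic scores of 129X1 vehicle prophylactic replicate 2 and therapeutic replicate 2 were 2.07 and 1.95, against 4.31 to 6.08 in the other vehicle libraries. Genes of other neprilysin substrates had a median of -0.48 (adjusted p = 0.0178, and 0.609 with an estimated correlation), with the calcitonin gene Calca (-5.24, adjusted p = 0.00284) and the kininogen Kng1 (-3.72) lower. The Calca value rests on 1 B6 therapeutic library, without which it was -1.08 (adjusted p = 0.311). By camera the neprilysin substrate list passed under prophylactic vehicle (adjusted p = 0.00202) but not therapeutic vehicle (0.372). The sympathetic list likewise passed under prophylactic vehicle alone (0.0168 against 0.151). The natriuretic peptide and cGMP list did not pass (median -0.25, adjusted p = 0.447), although Mme was higher and the cGMP phosphodiesterase Pde5a (-0.84) and Vasp (-0.60) were lower. Circadian genes did not pass as a list (median 0.17, adjusted p = 0.0998), while Per2 (0.88, adjusted p = 0.0103), Per3 (0.69), Tef (0.55) and Hlf (0.71) were higher. Oxidative stress genes (median -0.29, adjusted p = 0.552) held Cat (0.72) and Sod2 (0.79) higher and Hmox1 (-1.40) lower. The endothelial list (-0.19, adjusted p = 0.34) held Klf2 (-0.90) lower, mast cell genes (-0.26, adjusted p = 0.478) held Fcer1a (-2.10) lower and Tpsab1 (1.62) higher, and thyroid genes (-1.34, adjusted p = 0.59) held Tshr (-1.23) lower. The Tshr call was lost in 8 of 12 fits that left out 1 library, where it was as small as -0.46 (adjusted p up to 0.359), and those of Kng1, Pde5a, Vasp, Per3, Tef, Hlf, Cat, Sod2, Hmox1, Klf2 and Tpsab1 were lost in 2 to 10 of them (adjusted p up to 0.162), with Tpsab1 as large as 2.48. No gene passed in the lists of antigen presentation (-0.26, adjusted p = 0.124), cell cycle (0.29, adjusted p = 0.901), epithelium (1.24, adjusted p = 0.0998), red blood cells (0.73, adjusted p = 0.112), renin-angiotensin (-0.12, adjusted p = 0.593), skeletal muscle (0.80, adjusted p = 0.59) and T and NK cells (1.59, adjusted p = 0.147). Fry, the rotation test, passed 7 of 32 lists.

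The drug comparisons ask whether Sac/val or Val changed expression against vehicle, and whether Sac/val differed from Val, over the 4 strata and in each. Mme, Agtr1a and Npr3 did not pass in any of them. Across the 12 comparisons within strata, Mme ranged from -0.67 to 0.94 (smallest adjusted p 0.513), Agtr1a from -0.36 to 0.52 (smallest adjusted p 0.674) and Npr3 from -0.76 to 0.97 (smallest adjusted p 0.387). Their 95% intervals there reached from -1.68 to 1.90. In each of the 20 comparisons 0 genes passed by edgeR, and each gene named below for them is a value that did not pass that test.

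**Figure D4:**
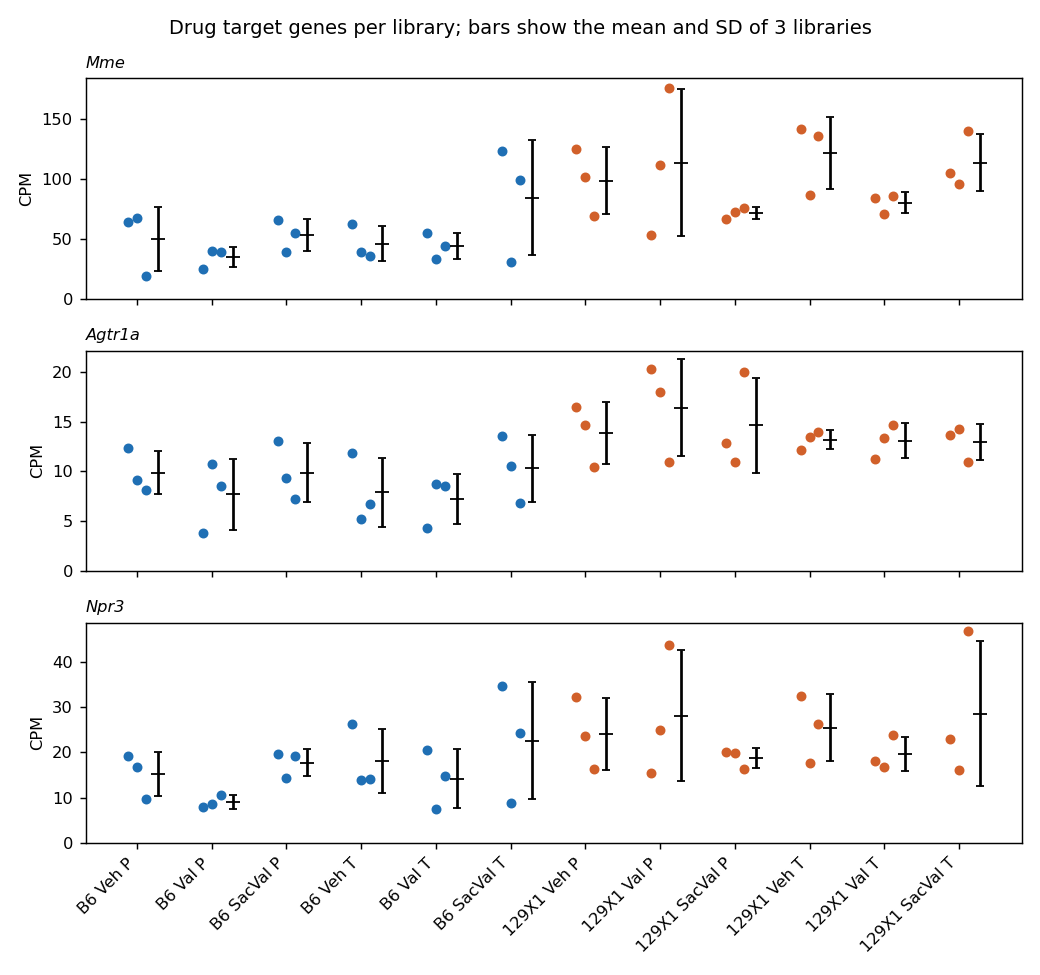
CPM of Mme, Agtr1a and Npr3 in each library of the 12 groups, 1 point per library, with the mean and SD of 3. Mme means run from 34.8 CPM (B6 Val prophylactic) to 122 CPM (129X1 vehicle therapeutic).

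For Sac/val against vehicle over the 4 strata (12 libraries each), the drug target genes showed small differences: Mme 0.10 (SE 0.22), Agtr1a 0.11 (SE 0.18) and Npr3 0.09 (SE 0.22; adjusted p = 1 each). In leave-one-out fits Mme ran from 0.004 to 0.20, Agtr1a from 0.03 to 0.21 and Npr3 from -0.05 to 0.18. With 3 list scores as covariates Agtr1a was at -0.013. The genes with the smallest p at or above 5 CPM were the developmental myosins Myh8 (3.00, SE 0.88; 40.5 ± 78.8 against 2.78 ± 2.56 CPM) and Myh3 (2.77, SE 0.94) and the antibody chain Ighg1 (-4.28, SE 1.32), with adjusted p = 1. Leaving out 1 library brought Myh3 to 1.17 and Ighg1 to -1.56. By edgeR 0 genes passed and 293 had an unadjusted p under 0.05, and DESeq2 called 11, immunoglobulin segments such as Ighv1-7 among them. Camera with the preset correlation passed 12 lists, 6 up and 6 down, and 0 of 32 passed with an estimated one. They included mitochondrial respiration (median 0.12, adjusted p = 0.00171), thyroid (-2.29, adjusted p = 0.00171), T and NK cells (-1.01, adjusted p = 0.00185), contractile smooth muscle (-0.34, adjusted p = 0.0045) and fibrillar matrix (0.27, adjusted p = 0.0157). Skeletal muscle had a median of 0.36 and a mean of 0.48 but a test direction of down (adjusted p = 0.00191). The thyroid value rests on B6 vehicle therapeutic replicate 3 and 129X1 vehicle therapeutic replicates 2 and 3. Their thyroid scores were 6.24, 3.505 and 2.08, against 0.239 or less in the other vehicle libraries. Under Sac/val 129X1 therapeutic replicate 3 stood apart (4.13). None of the 32 lists passed with an estimated correlation (smallest adjusted p = 0.882 with an estimated correlation) or by fry (smallest 0.93).

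Within strata, Sac/val against vehicle gave Mme log2 differences of 0.09 (B6 prophylactic), 0.88 (B6 therapeutic), -0.46 (129X1 prophylactic) and -0.10 (129X1 therapeutic), with SE of 0.43 to 0.44 and n = 3 per group. Agtr1a gave 0.00, 0.38, 0.08 and -0.02, and Npr3 gave 0.22, 0.32, -0.36 and 0.17. Over the fits that left out 1 library, in the same order, Mme ran from -0.30 to 0.36, 0.505 to 1.275, -0.66 to -0.25 and -0.29 to 0.03. Agtr1a ran from -0.255 to 0.18, 0.13 to 0.79, -0.22 to 0.25 and -0.10 to 0.085. Npr3 ran from -0.02 to 0.41, -0.12 to 0.70, -0.57 to -0.09 and -0.39 to 0.45. Signs turned with 3 list scores as covariates for Mme (-0.17), Agtr1a (-0.21) and Npr3 (-0.18) in B6 prophylactic, Agtr1a in B6 therapeutic (-0.001), Npr3 in 129X1 prophylactic (0.06) and Mme in 129X1 therapeutic (0.082). In B6 prophylactic the smallest p values belonged to the salivary genes Car6 (10.91, SE 2.07, adjusted p = 0.377) and Mucl2 (11.72, SE 2.58; 5080 against 1 counts, ratio 4710, interval 846 to 186000) and to Erdr1 (1.16, SE 0.40). Both salivary genes rest on 1 Sac/val library, without which Car6 was at -0.85 and Mucl2 at 0.40. In B6 therapeutic they were Calca (-7.71, SE 1.77, adjusted p = 0.951), the gluconeogenic Fbp1 (-3.47, SE 0.88) and the lung-rich receptor Ager (-4.87, SE 1.26), and without 1 vehicle library Calca was at 0.64. On leaving out 1 library Fbp1 was as small as -0.98 and Ager as small as -0.87. In 129X1 prophylactic they were the stress genes Gadd45a (2.58, SE 0.68), Hspa8 (0.51, SE 0.14) and Hsph1 (0.56, SE 0.16), and in 129X1 therapeutic Gm23935 (1.98, SE 0.75), the TGF-beta-induced Klf10 (0.38, SE 0.16) and Akip1 (0.30, SE 0.13), all at adjusted p = 1. Leaving out 1 library brought Gadd45a to 0.65, Klf10 to 0.25 and Akip1 to 0.19. EdgeR passed 0 genes in each stratum, with 141, 777, 471 and 101 genes at unadjusted p under 0.05, and DESeq2 called 16, 50, 3 and 0. Among the DESeq2 calls were Serpinb11 at 20.8 in B6 prophylactic and Ighv8-8 at -22.05 and Krt14 at -21.93 in B6 therapeutic. In 129X1 prophylactic Ighv1-54 was at -22.665. Log2 differences of that size exceed the 11.72 of Mucl2, the largest named here by edgeR, and edgeR passed none of these genes.

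The lists moved in different directions between those strata under the preset correlation. In B6 prophylactic 20 lists passed: fibrillar matrix (median -0.34), TGF-beta (-0.33) and mitochondrial respiration (0.15) each had an adjusted p of 9.72e-06 (smallest adjusted p = 0.558 with an estimated correlation). Beside them cytokines were lower (-0.47, adjusted p = 2.95e-05) and skeletal muscle higher (1.71, adjusted p = 0.000602), and brown fat had a median of -0.001 and a mean of 0.07 with a test direction of up. In B6 therapeutic 12 passed, with T and NK cell genes (-4.71) and cell cycle genes (-1.73) at 7.6e-08 and thyroid genes at -8.79 (adjusted p = 0.000965; smallest adjusted p = 0.671 with an estimated correlation), and 21 genes passed adjusted over the list alone. The T and NK value rests on vehicle replicates 2 and 3, with scores of 6.20 and 4.09 and Rag1 at 826 and 134.5 CPM, against 1.09 in vehicle replicate 1 and 0.869 to 0.903 under Sac/val. The cell cycle score of replicate 2 was 5.86 against 3.45 and 3.89. The thyroid value rests on vehicle replicate 3, with a thyroid score of 6.24 against -0.80 and -0.89 in the other vehicle libraries. In 129X1 prophylactic 17 passed, with fibrillar matrix (0.95, adjusted p = 1.2e-08), cytokines (1.01, adjusted p = 1.58e-05) and neutrophil genes (1.23, adjusted p = 0.000817) up and B and plasma cell genes down (-2.62, adjusted p = 0.0192; smallest adjusted p = 0.714 with an estimated correlation). The B and plasma cell score of vehicle replicate 2 there was 5.17, against -1.52 and 1.13 in the other vehicle libraries. In 129X1 therapeutic 1 passed, skeletal muscle (-0.23, adjusted p = 5.35e-13, and 0.98 with an estimated correlation). In the other 3 strata 0 genes passed adjusted over the list alone, and fry passed 0 lists in all 4 (smallest adjusted p 0.925, 0.981, 0.914 and 0.99).

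For Val against vehicle over the 4 strata, Mme was at -0.24 (SE 0.22, adjusted p = 0.986), Agtr1a at -0.07 (SE 0.18) and Npr3 at -0.31 (SE 0.22). In leave-one-out fits Mme ran from -0.36 to -0.16, Agtr1a from -0.15 to 0.035 and Npr3 from -0.43 to -0.22. With 3 list scores as covariates Mme was at 0.11. The smallest p values belonged to the macrophage lectin Cd209f (-1.25, SE 0.35), the secreted factor Metrn (0.45, SE 0.14) and Nudt3 (0.19, SE 0.06), with adjusted p = 0.986. EdgeR passed 0 genes, 453 had an unadjusted p under 0.05, and DESeq2 called 1, Serpinb11. Camera passed 12 lists, 2 up and 10 down, and 0 with an estimated correlation: interferon response was up (median 0.36, adjusted p = 1.04e-11), and adipocyte (-0.29) and endothelial genes (-0.16) were down at 7.82e-05 each. Schwann cell genes were up (0.25, adjusted p = 0.000919) and mitochondrial respiration down (-0.20, adjusted p = 0.0013). B6 Val prophylactic replicate 1 had an endothelial score of 5.01, against 6.29 and 6.27 in the other libraries of its group. Its adipocyte score was 7.78 against 8.67 and 8.91, while B6 vehicle prophylactic replicate 3 was lower still (7.61). The smallest adjusted p was 0.83 with an estimated correlation and 0.929 by fry, and 0 genes passed adjusted over the list alone.

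Within strata, Val against vehicle gave Mme log2 differences of -0.52 (B6 prophylactic), -0.06 (B6 therapeutic), 0.21 (129X1 prophylactic) and -0.60 (129X1 therapeutic), with SE of 0.43 and n = 3 per group. Agtr1a gave -0.36, -0.14, 0.24 and -0.01, and Npr3 gave -0.76, -0.35, 0.22 and -0.38. Over the fits that left out 1 library, in the same order, Mme ran from -0.915 to -0.25, -0.25 to 0.23, -0.26 to 0.55 and -0.79 to -0.47. Agtr1a ran from -0.68 to -0.03, -0.36 to 0.27, 0.06 to 0.47 and -0.10 to 0.09. Npr3 ran from -0.996 to -0.58, -0.71 to 0.02, -0.25 to 0.52 and -0.58 to -0.17. Signs turned with 3 list scores as covariates for Mme (0.48) and Npr3 (0.24) in B6 therapeutic and Npr3 in 129X1 therapeutic (0.17). In B6 prophylactic the smallest p values belonged to Erdr1 (1.53, SE 0.41), the water channel Aqp11 (4.01, SE 1.22) and Col2a1 (-3.63, SE 1.10), with adjusted p = 0.474, and on leaving out 1 library they were as small as 0.85, 0.29 and -2.28. In B6 therapeutic they were Calca (-6.22, SE 1.65), the epithelial Calml3 (-2.32, SE 0.71) and the endothelial proteoglycan Esm1 (-2.03, SE 0.64), with adjusted p = 1, and on leaving out 1 library Calca was at 2.13 and Calml3 at -0.37. In 129X1 prophylactic they were the atrial myosin chain Myl4 (3.02, SE 0.84), Pacs1 (-0.52, SE 0.15) and Rbx1 (0.40, SE 0.11), with adjusted p = 0.892, and Myl4 was as small as 0.82 on leaving out 1 library. In 129X1 therapeutic they were the receptor kinase Grk3 (-0.82, SE 0.27), the cochaperone Ptges3 (0.38, SE 0.13) and Gnl1 (0.37, SE 0.12), with adjusted p = 1. In each stratum edgeR passed 0 genes, with 1952, 252, 765 and 468 genes at unadjusted p under 0.05, and DESeq2 called 35, 0, 4 and 2. The DESeq2 calls included log2 differences of 22.29 (Serpinb11) and 23.17 (Slc13a2os) in B6 prophylactic and -20.91 (Skint10) in 129X1 prophylactic. Those in 129X1 therapeutic were Igkv14-100 (-21.99) and Sp7 (4.74).

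Under Val the lists that passed differed between strata. In B6 prophylactic 24 lists passed the preset camera, with T and NK cell genes at a median of 5.34 (adjusted p = 0.00164), cell cycle at 2.61 (adjusted p = 1.63e-05), interferon at 0.62 (adjusted p = 1.63e-05), fibrillar matrix at -0.42 (adjusted p = 2.09e-05) and skeletal muscle at -2.11 (adjusted p = 0.0229). The smallest adjusted p was 0.564 with an estimated correlation, and 19 genes passed adjusted over the list alone, 13 of them of the 17 T and NK cell genes. The T and NK cell and cell cycle values rest on Val replicate 1, with Rag1 at 1738 CPM and a T and NK score (mean log2 CPM) of 7.09, against 1.69 and 0.859 in the other Val libraries. Its cell cycle score was 7.16, against 3.37 and 3.19. Its fibrillar matrix score also stood apart, at 7.37 against 9.15 and 9.19 in the other Val libraries and 9.23 to 9.31 under vehicle. In B6 therapeutic 9 lists passed, with interferon (0.42) and Schwann cell genes (0.63) at 1.54e-14 and sympathetic genes at -0.38 (adjusted p = 3.9e-11; smallest adjusted p = 0.308 with an estimated correlation), and 7 genes passed adjusted over the list alone. The sympathetic scores of Val replicates 1 and 3 were 1.91 and 0.676, against 5.95 in replicate 2 and 4.72 to 5.58 under vehicle. There adventitial fibroblast genes had a median of 0.01 and a mean of -0.03 with a test direction of down. In 129X1 prophylactic 8 passed, with skeletal muscle at 1.77 (adjusted p = 4.33e-07), cell cycle at -1.62 (adjusted p = 1.54e-06) and T and NK cell genes at -2.41 (adjusted p = 6.61e-05; smallest adjusted p = 0.968 with an estimated correlation), and 0 genes passed adjusted over the list alone. Vehicle replicates 2 and 3 and Val replicate 3 had T and NK scores of 4.41, 5.75 and 3.84, against 0.003 or less in the other 3 libraries. Vehicle replicate 2 had a skeletal muscle score of 0.515, against 8.61 and 7.899 in the other vehicle libraries. In 129X1 therapeutic 9 passed, with adipocyte genes at -0.40 (adjusted p = 0.000158) and chondrocyte genes at 0.75 (adjusted p = 0.000243; 0.522 with an estimated correlation), and 4 genes passed adjusted over the list alone. The chondrocyte scores of Val replicates 2 and 3 were 3.14 and 2.42, against 0.772 in replicate 1. Skeletal muscle there had a median of 0.35 and a mean of -0.05 with a test direction of down. Fry passed 0 lists in all 4 strata (smallest adjusted p 0.657, 0.943, 0.955 and 0.698).

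For Sac/val against Val over the 4 strata, the comparison closest to neprilysin inhibition itself, Mme was at 0.35 (SE 0.22), Agtr1a at 0.17 (SE 0.18) and Npr3 at 0.40 (SE 0.22; adjusted p = 0.908). With 3 list scores as covariates the Mme sign turned (-0.011). In leave-one-out fits Mme ran from 0.25 to 0.46, Agtr1a from 0.08 to 0.255 and Npr3 from 0.26 to 0.52. The smallest p values belonged to the lipid-presenting Cd1d2 (-2.09, SE 0.62), Gm10499 (-2.76, SE 0.87) and Aqp11 (-1.68, SE 0.55), with adjusted p = 0.908, and on leaving out 1 library they were as small as -0.96, -1.22 and -0.74. EdgeR passed 0 genes, 491 had an unadjusted p under 0.05, and DESeq2 called 18, led by Ighv1-7. Camera passed 12 lists, 10 up and 2 down, and 0 with an estimated correlation: mitochondrial respiration (median 0.34, adjusted p = 4.18e-10), adipocyte (0.37, adjusted p = 8.72e-07), brown fat (0.45, adjusted p = 4.29e-05) and fibrillar matrix (0.14, adjusted p = 0.000165) were up, and interferon (-0.15, adjusted p = 8.72e-07) and cell cycle (-0.70, adjusted p = 0.0189) were down. The cell cycle scores of B6 Val prophylactic replicate 1 and B6 Val therapeutic replicate 1 (7.16 and 6.34) stood apart from those of the other B6 Val libraries (3.19 to 3.37). Sympathetic genes had a median of -0.07 and a mean of 0.001 with a test direction of up (adjusted p = 0.000878). The smallest adjusted p was 0.763 with an estimated correlation and 0.873 by fry, and 0 genes passed adjusted over the list alone.

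Within strata, Sac/val against Val gave Mme log2 differences of 0.61 (B6 prophylactic), 0.94 (B6 therapeutic), -0.67 (129X1 prophylactic) and 0.50 (129X1 therapeutic), with SE of 0.43 to 0.44 and n = 3 per group. Agtr1a gave 0.36, 0.52, -0.17 and -0.01, and Npr3 gave 0.97, 0.67, -0.58 and 0.54. Over the fits that left out 1 library, in the same order, Mme ran from 0.41 to 0.795, 0.57 to 1.34, -1.01 to -0.20 and 0.32 to 0.61. Agtr1a ran from 0.02 to 0.68, 0.25 to 0.75, -0.46 to 0.01 and -0.11 to 0.10. Npr3 ran from 0.87 to 1.11, 0.23 to 1.05, -0.87 to -0.10 and -0.01 to 0.83. Signs turned with 3 list scores as covariates for Npr3 in B6 therapeutic (-0.14) and Agtr1a in 129X1 prophylactic (0.10). In B6 prophylactic the smallest p values belonged to Car6 (11.30, SE 2.11, adjusted p = 0.3), Mucl2 (8.62, SE 2.13) and the lysosomal Ppt1 (-0.67, SE 0.19). Without 1 Sac/val library Car6 was at -0.45 and Mucl2 at -2.69, and on leaving out 1 library Ppt1 was as small as -0.33. In B6 therapeutic they were Tbx6 (-0.93, SE 0.26, adjusted p = 0.775), the potassium channel Kcnj15 (-1.55, SE 0.46) and Cd1d2 (-4.36, SE 1.41; 5 against 101 counts, ratio 22.6, interval 9.38 to 71.1; as small as -1.84 on leaving out 1 library). In 129X1 prophylactic they included the mast cell receptor Kit (-0.82, SE 0.19) and Neurl1b (0.91, SE 0.25), with adjusted p = 0.805. In 129X1 therapeutic they were 4930481A15Rik (1.60, SE 0.35), Col2a1 (-3.35, SE 1.12) and the B cell receptor chain Ighd (3.72, SE 1.54), with adjusted p = 1, and on leaving out 1 library the last 2 were as small as -2.004 and 1.97. In these strata edgeR passed 0 genes, with 2400, 801 and 866 genes at unadjusted p under 0.05 in the first 3 and 0.762 percent of genes in 129X1 therapeutic, and DESeq2 called 17, 20, 7 and 1. The DESeq2 calls included log2 differences of -23.065 (Slc13a2os), -24.03 (Ighv1-7), 20.755 (Skint10) and 18.39 (Igkv14-100), in the same order of strata.

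The lists that passed in Sac/val against Val also differed between strata. In B6 prophylactic 13 lists passed the preset camera, with cell cycle at -2.92 and mitochondrial respiration at 0.62 (adjusted p = 2.86e-07 each), skeletal muscle at 3.77 and T and NK cell genes at -5.29 (adjusted p = 0.000533; 0.791 with an estimated correlation). There 36 genes passed adjusted over the list alone, 22 of 24 in the cell cycle list and 14 in the T and NK list. The same Val replicate 1 carries the cell cycle and T and NK values, with a cell cycle score of 7.16 against 3.37 and 3.19 in the other Val libraries. In B6 therapeutic 12 passed, with cell cycle at -2.05 (adjusted p = 1.11e-07), mitochondrial respiration at 0.70 (adjusted p = 2.01e-07), mast cell genes at 1.11 (adjusted p = 2.48e-07) and renin-angiotensin genes at 0.17 (adjusted p = 0.0472; 0.699 with an estimated correlation), and 16 genes passed adjusted over the list alone. There Val replicate 1 stood apart, with a T and NK score of 6.40 against 1.24 and 1.47. Adventitial fibroblast genes had a median of -0.03 and a mean of 0.05 with a test direction of up. In 129X1 prophylactic 17 passed, with cell cycle at 2.15 (adjusted p = 4.77e-12), skeletal muscle at -2.32 (adjusted p = 1.33e-09), fibrillar matrix at 0.80 (adjusted p = 3.85e-06) and cytokines at 1.21 (adjusted p = 9.77e-06; 0.59 with an estimated correlation), and 2 genes passed adjusted over the list alone. Sac/val replicates 1 and 2 had cell cycle scores of 5.04 and 5.645 both with Rag1 at or above 10 CPM (up to 418 CPM). Val replicates 1 and 2 had scores of 1.39 and 1.34 with Rag1 at 0.368 and 0.18 CPM. In 129X1 therapeutic 7 passed, with B and plasma cell genes at 1.88 (adjusted p = 3.36e-07) and chondrocyte genes at -0.72 (adjusted p = 7.74e-07; 0.106 with an estimated correlation), and 4 genes passed adjusted over the list alone. The B and plasma cell score of Sac/val replicate 1 there was 3.85, against 1.46 and 1.38 in the other Sac/val libraries. Fry passed 0 lists in all 4 strata (smallest adjusted p 0.668, 0.614, 0.545 and 0.695).

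The regimen comparison asks whether therapeutic and prophylactic vehicle groups differ (6 libraries each). Mme was at 0.09 (SE 0.31), Agtr1a at -0.20 (SE 0.25) and Npr3 at 0.17 (SE 0.31; adjusted p = 1 each). In leave-one-out fits Mme ran from -0.11 to 0.23, Agtr1a from -0.40 to -0.09 and Npr3 from -0.02 to 0.30. With 3 list scores as covariates Mme was at -0.024 and Npr3 at -0.13. Among the smallest p values were those of Ager (3.58, SE 0.84) and Calml3 (1.77, SE 0.49), with adjusted p = 1, as small as 1.58 and 0.79 on leaving out 1 library. EdgeR passed 0 genes, 297 had an unadjusted p under 0.05, and DESeq2 called 32. Camera passed 11 lists, 5 up and 6 down, and 0 with an estimated correlation, with skeletal muscle at 1.08 (adjusted p = 1.52e-10), T and NK cell genes at 1.998 (adjusted p = 1.83e-07) and thyroid genes at 5.72 (adjusted p = 1.01e-05; 0.845 with an estimated correlation). The thyroid value rests on B6 therapeutic replicate 3 and 129X1 therapeutic replicates 2 and 3, with Tg at 42480, 3292 and 1345 CPM. Their thyroid scores were 6.24, 3.505 and 2.08, against 0.239 or less in the other vehicle libraries. The T and NK scores of B6 therapeutic replicates 2 and 3 were 6.20 and 4.09, against 1.03 to 1.225 in the other B6 vehicle libraries. Skeletal muscle scores were lowest in 129X1 prophylactic replicate 2 (0.515) and B6 prophylactic replicate 1 (3.75). Fry passed 0 (smallest 0.982), and 7 genes passed adjusted over the list alone, 6 of them thyroid genes.

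The interactions ask whether a drug difference depends on strain (129X1 minus B6) or on regimen (therapeutic minus prophylactic). For Sac/val and strain, Mme was at -0.76 (SE 0.43, adjusted p = 0.952), Agtr1a at -0.16 (SE 0.36) and Npr3 at -0.36 (SE 0.44), and the smallest p values belonged to Calca (5.85, SE 1.48), B230206H07Rik (-1.22, SE 0.36) and the secretory stress factor Manf (0.68, SE 0.21). Calca was as small as 1.69 on leaving out 1 library. For Sac/val and regimen, Mme was at 0.58 (SE 0.43, adjusted p = 1), Agtr1a at 0.14 and Npr3 at 0.31, and the smallest p values belonged to the muscle troponin Tnnt1 (-4.47, SE 1.39), Fbp1 (-2.52, SE 0.82) and Ager (-3.01, SE 1.11), as small as -2.68, -1.27 and -1.01 on leaving out 1 library. For Val and strain, Mme was at 0.10 (SE 0.43), Agtr1a at 0.37 and Npr3 at 0.48, and the smallest p values belonged to Col2a1 (3.88, SE 1.04), the cardiac actin Actc1 (4.51, SE 1.30) and Myl4 (2.73, SE 0.80; 1.63 at its smallest on leaving out 1 library), with adjusted p = 0.633. For Val and regimen, Mme was at -0.17 (SE 0.43), Agtr1a at -0.02 and Npr3 at -0.10, and the smallest p values belonged to Galnt18 (0.69, SE 0.21), Calml3 (-2.11, SE 0.68) and Fbp1 (-2.49, SE 0.81), with adjusted p = 1, the last 2 as small as -1.14 and -1.25 on leaving out 1 library. Over the fits that left out 1 library Mme, Agtr1a and Npr3 ran from -0.96 to -0.57, -0.37 to -0.03 and -0.64 to -0.14 for Sac/val and strain and from 0.39 to 0.775, 0.01 to 0.34 and 0.04 to 0.50 for Sac/val and regimen. They ran from -0.135 to 0.29, 0.16 to 0.53 and 0.24 to 0.66 for Val and strain and from -0.34 to 0.06, -0.19 to 0.19 and -0.28 to 0.14 for Val and regimen. Signs turned with 3 list scores as covariates for Agtr1a (0.19) and Npr3 (0.28) for Sac/val and strain, Agtr1a for Sac/val and regimen (-0.078), Mme for Val and strain (-0.005) and Mme (0.24) and Npr3 (0.44) for Val and regimen. EdgeR passed 0 genes in each, with 651, 156, 960 and 215 genes at unadjusted p under 0.05 in that order, and DESeq2 called 5, 5, 14 and 0.

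Camera with the preset correlation passed 16, 12, 13 and 14 lists in these interactions, and 0 passed with an estimated correlation. Single libraries stood apart in several of these lists. The cell cycle scores of B6 Val prophylactic replicate 1 and B6 Val therapeutic replicate 1 were 7.16 and 6.34, against 3.19 to 3.37 in the other B6 Val libraries. Sympathetic scores were 1.39 and 1.91 in those same libraries and 0.676 in B6 Val therapeutic replicate 3, against 5.56 to 6.18 in the other B6 Val libraries. They were 2.07 and 1.95 in 129X1 vehicle prophylactic replicate 2 and therapeutic replicate 2. B6 vehicle therapeutic replicates 2 and 3 had T and NK scores of 6.20 and 4.09, against 1.03 to 1.225 in the other B6 vehicle libraries. For Sac/val and strain, adipocyte (median -0.64), cell cycle (1.54) and fibrillar matrix genes (0.72) each had an adjusted p of 7.32e-07 (0.722 with an estimated correlation). For Sac/val and regimen, skeletal muscle (-0.42, adjusted p = 8.79e-08), mast cell (0.58, adjusted p = 1.65e-06) and T and NK cell genes (-2.11, adjusted p = 5.9e-05) led (0.894 with an estimated correlation). For Val and strain, sympathetic genes were at 1.46 (adjusted p = 6.38e-10, and 0.775 with an estimated correlation), cell cycle at -1.97 (adjusted p = 0.000108) and interferon at -0.38 (adjusted p = 0.000407; 0.879 with an estimated correlation). For Val and regimen, skeletal muscle was at -0.33 (adjusted p = 1.66e-07), TGF-beta at 0.46 (adjusted p = 2.65e-05; 0.592 with an estimated correlation) and chondrocyte genes at 0.98 (adjusted p = 5.31e-05, and 0.377 with an estimated correlation). Fry passed 0 lists in each (smallest 0.75, 0.982, 0.434 and 0.941), and 1, 0, 2 and 4 genes passed adjusted over the list alone.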

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

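Chosen only after their results were seen were the tests of thymus transcripts, of tissue content behind the strain calls and the mitochondrial list, of read loss against the reference and of the Ndufs5 copy, and every test with sample quality weights, the random moves of the 6 scores among them. The gene lists that differ by the interaction test are singled out because the drug difference is tested for dependence on strain or regimen. Camera with the preset correlation passed 16 lists for Sac/val and strain, 12 for Sac/val and regimen, 13 for Val and strain and 14 for Val and regimen, and 0 passed with an estimated correlation (smallest adjusted p 0.722, 0.894, 0.775 and 0.377). In the same interactions edgeR passed 0 genes, with 651, 156, 960 and 215 at unadjusted p under 0.05 and 5, 5, 14 and 0 called by DESeq2. All 100 of 100 splits gave as many genes, as any split must against a count of 0, so they say nothing about chance (highest other counts 658, 0, 7 and 19).

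Other splits of the libraries were run for each count of genes. For strain 1 of 100 splits, the real split itself, reached 2522 genes, and the highest other count was 776. This argues against chance for that count. It does not exclude chance, since 1 of 100 is the smallest share that 100 splits can give. At unadjusted p under 0.05, 2 of 100 splits reached the real 5358 genes, and the other split had 5497. For the real count of 0, all 100 of 100 splits gave as many for Sac/val against vehicle (highest other 3428), Val against vehicle (2029) and Sac/val against Val (4146) over 4 strata, and for regimen (262). Any split reaches a count of 0, so these say nothing about chance. For each drug comparison over 4 strata, 5 of the other splits called any gene, and the median of the other splits was 0. Splits with 3428, 2029 and 4146 genes were thus rare, and a structure of the samples other than treatment was not tested. Within strata 10 splits are too few for a share under 0.05: 10 of 10 gave as many as the real 0, with highest others of 0, 0, 0 and 0 for Sac/val against vehicle, 0, 1, 473 and 0 for Val against vehicle and 0, 7, 2 and 3 for Sac/val against Val (B6 prophylactic, B6 therapeutic, 129X1 prophylactic, 129X1 therapeutic).

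Transcripts of developing T cells appeared in part of the libraries, with Rag1 at or above 10 CPM in 16 of 36. In the 16 libraries at or above 10 CPM of the T cell gene Cd3e, a set chosen without regard to Rag1, the median ratio of Rag1 to Cd3e was 3.49, which argues against mature T cells that entered the artery as the main source, since these do not express Rag1. In 1 of them, 129X1 vehicle therapeutic replicate 2, the ratio was 0.0671, so mature T cells are not excluded there. All 16 held over 3 counts of both Foxn1 and Psmb11, genes of thymic epithelium, against 5 of the other 20, a result consistent with thymus tissue taken with the artery. The share of such libraries by strain (12 of 18 and 4 of 18) stays open, since a strain difference in the position or size of the thymus was not tested.

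The strain calls were weighed against content, read loss and shared reads. Of the 2522 genes, 944 still passed with the skeletal muscle, adipocyte and Schwann cell scores as covariates. This argues against a difference in fat, muscle and nerve content as the whole cause. For the mitochondrial respiration list the median moved from 0.78 to 0.088, as such a difference would give. Thymus and lymphoid content is not in those scores. With the 6 scores, which include T and NK cell and B and plasma cell genes, 1151 of the 2522 still passed. Loss of 129X1 reads against the B6 reference cannot be told apart. In the main fit 48.1 percent of the called genes were lower in 129X1. The share was 62.6 percent with only the vehicle libraries, the highest, and 55.5 percent with sample quality weights. It was 45.5 percent by DESeq2 and 40.8 percent, the lowest, without 129X1 vehicle prophylactic replicate 3. Scaling also centres the ratios, which hides a broad loss. For Ndufs5 (lower) and BC002163 (higher), which share 99.4 percent of 319 bases, the summed CPM of the pair differed by 0.856 (SE 0.256), consistent with reads shared between a gene and its processed copy. A strain difference in the artery itself stays open and was not tested apart from these.

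Drug calls appeared where libraries were weighted by their quality, with weights from 0.091 (B6 Val prophylactic replicate 1) to 3.95 (B6 Sac/val therapeutic replicate 3). Voom with these weights called 453 genes for Val against vehicle over 4 strata, and 25 of 100 splits gave as many (highest other 6746), so chance cannot be excluded. With 6 list scores as covariates 0 of the 453 still passed, but 89 of 100 random moves of the scores between libraries also left 0. By that count a difference in tissue content cannot be told apart from the cost of any 6 covariates. The median difference of the 453, in its first direction, fell from 0.537 to 0.148 with the scores. The random moves gave a median of 0.435, and 1 of 100 gave as small a value. For the size of the difference in these 453 genes, this argues against the cost of any 6 covariates as the whole cause. For the interaction of Sac/val with strain it called 229, and 19 of 100 splits gave as many (highest other 7756), so chance cannot be excluded. Within strata 10 splits are too few for a share under 0.05: 103 genes for Sac/val in B6 therapeutic (2 of 10 splits, highest other 105), 815 for Val in 129X1 prophylactic (3 of 10, highest other 1568) and 582 for Val in 129X1 therapeutic (2 of 10, highest other 775). An effect of the drugs stays open and these tests leave it untested apart from content.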

How the results depend on the processing

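Chosen only after the results were seen were the tests with 6 list scores, sample quality weights, a robust prior, without the libraries at or above 10 CPM of Rag1, and the leave-one-out fits of the strain lists. So were the strain contrasts within 1 regimen and in drug-treated libraries. The other settings, the 21 comparisons and the gene lists were fixed before the data were examined. Of 474 summary counts under settings fixed earlier, 399 kept within 1.5 times, and of 91 under those added later 76 did. The main gene count was 0 in 20 of the 21 comparisons, and a 0 that stayed 0 was counted as kept. These shares therefore say little about the counts above 0. The strain count of 2522 was 2494 with DESeq2 size factors, 3331 by DESeq2, 1933 without a filter, 2425 with only the vehicle libraries (907 higher, 1518 lower), 3461 with the animal number and 2508 with a robust prior. It moved to 1093 with 3 list scores, 1513 with 6 list scores, 6172 with sample quality weights (2745 higher, 3427 lower) and 715 without the libraries with Rag1, a fit of 4 B6 against 2 129X1 vehicle libraries. Leaving out 1 library gave 1438 to 2844, with 1438 without B6 vehicle prophylactic replicate 3, 1530 without 129X1 vehicle prophylactic replicate 1 and 1478 without 129X1 vehicle therapeutic replicate 1; the cause was not tested. Of the 88 genes named for strain, 53 lost the call with 3 list scores, 43 with 6 (and Ms4a1, whose sign turned), 62 without the libraries with Rag1, 21 with only the vehicle libraries, 11 without a filter and 1 with DESeq2 size factors, and 1 gained it with 6. Mme lost it with 3 scores (0.40), with 6 (0.45) and without the libraries with Rag1 (0.90). No sign among them changed on leaving out a library. In the other comparisons edgeR passed 0 genes under size factors, no filter, only the libraries compared, the animal number and a robust prior, and in the 14 that could be fitted without the libraries with Rag1. DESeq2 called 11 (Sac/val), 1 (Val) and 18 (Sac/val against Val) over 4 strata. In B6 prophylactic, B6 therapeutic, 129X1 prophylactic and 129X1 therapeutic it called 16, 50, 3 and 0 for Sac/val, 35, 0, 4 and 2 for Val and 17, 20, 7 and 1 for Sac/val against Val. It called 32 for regimen and 5, 5, 14 and 0 for the interactions. Sample quality weights called 1 (Sac/val) and 453 (Val) over 4 strata, 103 and 1 for Sac/val in B6 therapeutic and 129X1 therapeutic, 815 and 582 for Val in 129X1 prophylactic and 129X1 therapeutic, 1, 3 and 1 for Sac/val against Val in B6 prophylactic, B6 therapeutic and 129X1 therapeutic, and 229 for Sac/val and strain. With those weights and 6 list scores, Sac/val against Val in 129X1 prophylactic gave 525. With 3 list scores 1 gene passed (Gm45110, Sac/val against Val in 129X1 prophylactic), and with 6 list scores 2 there (Camk4 and Cdhr2) and 1 in 129X1 therapeutic (4930481A15Rik), all named after their values were seen. Leaving out 1 library gave 0 to 2 for Sac/val against vehicle and against Val in B6 prophylactic (2 without Sac/val replicate 1 and 2 without Sac/val replicate 3, Car6 and Wfdc12), 0 to 1 for Sac/val in B6 therapeutic (1 without vehicle replicate 2, Gprc5a) and 0 to 0 in every other comparison. In these fits 1 group has 2 libraries and the spread is pooled over all groups. Among 120 genes named there, 30 changed sign in a leave-one-out fit, 7 gained a call by DESeq2, and under settings added later 27 changed sign with 6 list scores, 18 with sample quality weights and 15 of 84 without the libraries with Rag1. These added settings are tabulated beside the planned ones for the strain genes alone, a choice made after those values were seen. The contrasts that use the 129X1 Val therapeutic group could not be fitted without the libraries with Rag1, since all 3 of its libraries were left out. Signs reversed with 3 list scores, none past the threshold: Npr3 in strain (-0.21, and -0.14 with 6 scores, where Ms4a1 was -0.14); Agtr1a in Sac/val (-0.013), Mme in Val (0.11) and Mme in Sac/val against Val (-0.011) over 4 strata; Mme (-0.17), Agtr1a (-0.21, and -0.02 with the animal number) and Npr3 (-0.18) in Sac/val B6 prophylactic; Agtr1a in Sac/val B6 therapeutic (-0.001). Further ones were Npr3 in Sac/val 129X1 prophylactic (0.06), Mme in Sac/val 129X1 therapeutic (0.082), Mme (0.48) and Npr3 (0.24) in Val B6 therapeutic, Npr3 in Val 129X1 therapeutic (0.17), Npr3 in Sac/val against Val B6 therapeutic (-0.14) and Agtr1a in Sac/val against Val 129X1 prophylactic (0.10). In the regimen comparison Mme (-0.024) and Npr3 (-0.13) reversed, in the interactions Agtr1a (0.19) and Npr3 (0.28) for Sac/val and strain, Agtr1a for Sac/val and regimen (-0.078), Mme for Val and strain (-0.005) and Mme (0.24) and Npr3 (0.44) for Val and regimen. Agtr1a in Sac/val against Val 129X1 therapeutic was 0.005 with size factors, 0.005 by DESeq2, 0.006 without a filter and 0.023 with only the libraries compared, and Agtr1a for Val and regimen 0.001 with only the libraries compared; the cause was not tested. Of the lists, 0 passed with an estimated correlation in any of the 21 comparisons, and fry passed 7 for strain and 0 in the other 20. With 3 list scores 7 passed for strain, 19 for Val over 4 strata, 3 for Sac/val in 129X1 therapeutic, 19 for Val in B6 therapeutic, 8 for Sac/val against Val in B6 prophylactic and 7 for Val and regimen, and a prior count of 0.5 moved no list count over 1.5 times. Leaving out 1 library gave 13 to 19 strain lists. Without the libraries with Rag1 the adipocyte (median 0.76), brown fat (0.78), chondrocyte (-0.96) and Schwann cell lists (-0.20) no longer passed camera. The antigen presentation (-0.47), epithelial (5.23) and cell cycle lists (-1.15) passed there and not in the main fit. The test direction of the cell cycle list was down there and up in the main fit. No paired analysis was possible because animals in different groups carry different numbers. Depth was 18.96 M to 28.97 M counts per library and no setting lowered it.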

Other observations

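The tests in this part, the strain contrast in drug-treated libraries and the sums of copy pairs, were chosen only after the results were seen. In the 24 drug-treated libraries (12 per strain) many strain differences of the vehicle libraries recurred. No list scores were covariates in this contrast, so recurrence does not separate strain from tissue content or from read loss against the reference. Fcgr1 was lower in 129X1 by -2.33 (SE 0.31, edgeR adjusted p = 2.66e-06), Bst2 by -1.59 (SE 0.17, adjusted p = 7.6e-08), Lox by -1.24 (SE 0.31, adjusted p = 0.00492), Ccl7 by -1.96 (SE 0.44, adjusted p = 0.0021) and Arg1 by -2.90 (SE 0.55, adjusted p = 0.000317). Mme (0.86, SE 0.22, adjusted p = 0.00551), Nnt (0.62, SE 0.14, adjusted p = 0.00138) and Timp4 (1.203, SE 0.23, adjusted p = 0.000316) were higher. Agtr1a (0.715, SE 0.18, adjusted p = 0.00524) and Npr3 (0.63, SE 0.22, adjusted p = 0.0439), which did not pass in the vehicle libraries, also passed here as higher in 129X1. EdgeR passed 3998 genes there, 2013 higher and 1985 lower, and of the 2522 vehicle calls 1988 passed with the same sign and 0 with the opposite sign. Interferon response genes were lower in 17 of 19 (median -1.61, camera adjusted p = 2.79e-11), cytokine genes in 15 (median -1.24, adjusted p = 1.04e-05) and macrophage genes in 11 (median -0.82, adjusted p = 0.00012), each at an adjusted p = 0.937 with an estimated correlation. Fibrillar matrix genes had 5 lower and a smaller median of -0.53 (adjusted p = 0.0154, and 0.937 with an estimated correlation). Several lists that camera passed under vehicle did not pass here. They were those of adipocyte (adjusted p = 0.06), B and plasma cell (0.125), other neprilysin substrate (0.213) and neutrophil genes (0.271). Adventitial fibroblast (0.536) and chondrocyte genes (0.774) did not pass either. The sympathetic list had a test direction of up (median 0.048, adjusted p = 0.538).

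Some genes called in the vehicle libraries did not pass in the drug-treated ones, and whether the library sets differ was not tested. The clock genes Per2 (0.13, SE 0.16, adjusted p = 0.618), Per3 (0.23, SE 0.14, adjusted p = 0.267), Tef (0.23, SE 0.12, adjusted p = 0.202) and Hlf (0.33, SE 0.16, adjusted p = 0.143) kept their sign at smaller values. So did Eln (-0.57, SE 0.54, adjusted p = 0.519), Calca (-0.05, SE 0.69, adjusted p = 0.982), Egr1 (-0.53, SE 0.21, adjusted p = 0.0689) and Col2a1 (-1.37, SE 0.52, adjusted p = 0.0584).

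Of the copy pairs, Eno1 with Eno1b (99.5 percent identical over 1652 bases) had a summed difference of 0.41 (SE 0.30), where Eno1b alone differed by 10.60. Rps3a1 with Rps3a3 (98.9 percent over 795 bases) had a summed difference of -0.92 (SE 0.10), with Rps3a1 at 77.7 CPM in 129X1 and 344 CPM in B6. With sample quality weights and 6 list scores the strain comparison gave 1889 genes, of which 1477 were shared with the 6172 called without the scores.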
